A study of Rattus norvegicus with 19 samples.

How the data were processed

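RNA was measured in brain tissue of 19 female Wistar rats, each the offspring of a father from 1 of 4 groups: control, HFD (high-fat diet), ELS (early life stress, which the series text describes as separation from the mother) or ELS-HFD (both exposures). Every offspring was itself on a chow diet, per the labels. The sample labels give brain as the tissue and whole tissue lysate as the material, and the series text narrows the tissue to the amygdala. The series text speaks of male rats, whereas each sample label says female offspring; the sample labels were followed. The animals were tested on an elevated plus maze on postnatal day 57 ± 1, per the labels' protocols. About 400 ng of RNA went into each library, with enrichment of polyadenylated RNA and random priming.

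The authors deposited whole-number counts of reads per Ensembl gene ID, with no normalization, per the file headers and the values. The submitters' processing notes name the Rnor_6.0 build and DESeq2, with no version. The aligner, its settings and the annotation release are not given in the sources used here, and neither is the handling of strand or of reads that match several genes. Counts of overlapping or near-identical genes therefore carry an uncertainty that was not measured here. The table held 32883 gene IDs, of which 23224 had a count in at least 1 library. All 19 columns were matched to samples by the number in the sample description.

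The table of gene symbols used here pairs 0 of the 32883 IDs with a symbol, since its column for Ensembl IDs is filled in 0 rows, and the deposited file does not pair IDs with names. No gene is named for that reason. The 40 gene lists and the panel of stress genes fixed before the data were examined need symbols and were not tested, and checks of GC content or gene length were not made. The rule for named genes also asked for a symbol, so it could not be applied. In its place 4 IDs are printed. Of these, 3 had the smallest p in a comparison (ELS-HFD against ELS, paternal ELS averaged over diets, and paternal HFD averaged over early life), and 1 is the most abundant member of a set of IDs described in the report. All 4 were chosen after their values were seen.

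Library totals ran from 7034837 to 20266594 counts, with a median of 14027828. IDs were kept by the default filter of edgeR (filterByExpr on the 4 groups), which left 15372 IDs holding at least 99.9% of the counts of every library. Library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood F test (version 4.0.16, R 4.3.3) in 1 fit over the 19 libraries with the group as the only term, and IDs were called at a Benjamini-Hochberg adjusted p under 0.05. The 8 contrasts were the differences HFD against control, ELS against control, ELS-HFD against control, ELS-HFD against ELS and ELS-HFD against HFD, the interaction of both exposures, and the effect of each exposure averaged over the other. The standard error of a log2 fold change was taken as its size divided by the square root of F. The labels give no litter, father, library batch or date, so p-values measure the spread between these animals, some of which may share a father or litter.

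Log2 CPM values (CPM is the count scaled by the TMM-adjusted library size) were computed with a prior count of 2. Principal components used all 15372 IDs. Sets of co-varying IDs were formed without the group labels: IDs with an SD over 1 on the log2 scale and at least 5 CPM in some library (344 IDs) were clustered by average linkage on 1 minus Pearson's r, the tree was divided at 0.35, and sets of at least 10 IDs were kept. These sets, the principal components and the share of counts in the 10 most abundant IDs were compared between groups by exact permutation, two-sided, in a family of 48 tests with Benjamini-Hochberg adjustment. For the averaged effects and the interaction, labels were permuted within each stratum. This assumes no difference in either stratum, so for the interaction it is not an exact test of equal differences in both. Distances between whole profiles were compared by permutation of the share of variance between groups (6 tests, 100000 permutations for the 4 groups and exact for the pairs). The sets and the tests on them were chosen after the data were examined.

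The edgeR procedure was tested on simulated counts drawn from the means, totals and dispersions of these libraries, with 200 IDs of at least 1 CPM changed. In the simulated contrast of HFD against control (15207 IDs tested), 65% of IDs changed by a fold of 2 and 95% of those changed by a fold of 4 were recovered. For ELS against control (15236 IDs tested) the shares were 69% and 95%, for ELS-HFD against ELS (15197 IDs tested) 67% and 94%, and for paternal HFD averaged over early life (15217 IDs tested) 88% and 100%. False calls were 12 of 172, 7 of 171, 10 of 171 and 15 of 203 in these contrasts, in that order. Simulated IDs vary independently of each other, which the real ones do not.

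Alternatives fixed before the data were examined were RLE scaling, DESeq2 (1.42.0) with its default filters, limma-voom (3.58.1), no filter, a filter of at least 1 CPM in at least 4 libraries, robust dispersions, a fit to only the groups compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), and each library left out in turn. Other alternatives were added after seeing the data: a fit without HFD replicate 1 and ELS-HFD replicates 2 and 3, limma-voom with sample weights, and another 2 settings of DESeq2's filters. DESeq2 was run on the 15372 filtered IDs for the planned setting. For each contrast, 100 splits of the samples, the real one included, were refitted, and all 56 splits of ELS-HFD against ELS without the 3 libraries named above. Library pairs were also compared with sampling noise after all libraries were thinned to 7034837 counts. The closest of the 171 pairs, ELS-HFD replicates 2 and 3, differed by 2.23 times the variance of sampling, next to 2.40 for the second closest pair, so no pair was treated as 1 library. The library next closest to each of these 2 was control replicate 5, at 7.86 and 7.90, so they stood together and apart from the rest. They were counted as separate animals in every contrast. The labels do not show whether they share a litter or a batch, so their independence was not tested.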

Results

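Counts were available for 19 libraries from the brains of female rats: 5 daughters of control fathers, 4 of HFD fathers, 5 of ELS fathers and 5 of ELS-HFD fathers. The largest library was control replicate 1 with 20266594 counts, and the smallest was ELS-HFD replicate 2 with 7034837. The other control libraries held between 13184500 and 16510606, the HFD libraries between 10092297 and 14493508, the ELS libraries between 12219864 and 16944395, and the remaining ELS-HFD libraries between 11340358 and 14766188. Between 17579 and 18986 gene IDs had a count in each library. The files do not pair IDs with gene names, so IDs are described by their values and by the sets in which they varied together.

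The largest differences among libraries were carried by few of them. The first principal component held 32.9% of the variance, with HFD replicate 1 at 113.69, ELS-HFD replicate 2 at 49.23 and ELS-HFD replicate 3 at 47.82, and the other 16 libraries between -29.02 and 10.59. In HFD replicate 1 the 10 most abundant IDs took 25.62% of the counts, against 8.74% to 16.73% in the other libraries. The second component held 18.8% and separated all 5 control libraries (2.01 to 40.4) from all 4 HFD libraries (-27.54 to -15.9). The 4 groups explained 23.6% of the variance between whole profiles (permutation p = 0.0407, adjusted p = 0.0833 over 6 tests).

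**Figure D1:**
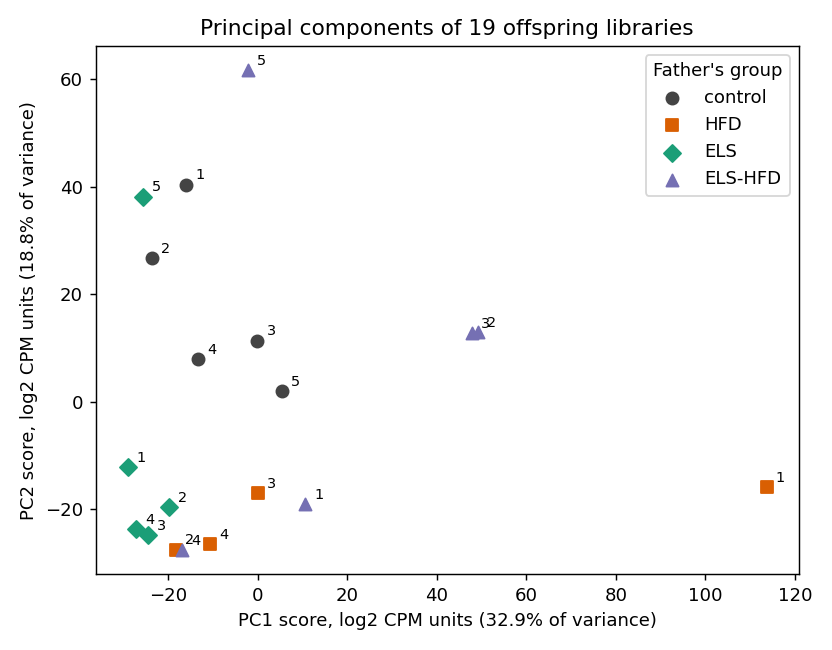
Scores of the 19 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis, a marker shape and color for each father's group and the replicate number beside each point. HFD replicate 1 lies at 113.69 on the first component, and ELS-HFD replicates 2 and 3 lie at 49.23 and 47.82.

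Clustering of 344 variable IDs without the group labels gave 3 sets. Set A held 137 IDs and took up to 1.89% of a library's counts. Its lead ID, ENSRNOG00000016275, was at 321 to 4632 CPM in the control libraries and at 0.684 to 2.59 CPM in the HFD libraries. Set B held 81 IDs and was lowest in HFD replicate 1 (mean log2 CPM 0.15) and in ELS-HFD replicates 2 and 3 (1.66 and 1.76). Set C held 19 IDs, and none of its differences between groups had an exact permutation p under 0.05.

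The comparison of HFD with control asks whether a father's diet is followed by a difference in the daughters' brains. Set A was lower in all 4 daughters of HFD fathers than in all 5 daughters of control fathers. Its mean log2 CPM was -0.27 ± 0.18 (SD, n = 4) against 2.19 ± 0.92 (SD, n = 5), a difference of -2.46 (exact permutation p = 0.00794, the smallest that 126 splits can give, adjusted p = 0.0572 over 48 tests). ENSRNOG00000016275 averaged 1.78 ± 0.852 CPM (SD, n = 4) and 1861 ± 1718 CPM (SD, n = 5), with an edgeR log2 fold change of -10.00 ± 3.09 (SE) and an adjusted p of 0.616. Its adjusted p was 0.000393 with DESeq2 and 0.0129 in an edgeR fit to these 2 groups alone, and ran from 0.00039 to 1.00 over all alternatives. The group explained 21.3% of the variance between whole profiles (exact permutation p = 0.00794, adjusted p = 0.0476 over 6 tests). The exact permutation p was 0.0857 without control replicate 1, 0.0571 without control replicate 2 and 0.0536 without HFD replicate 3. With set A left out, that share was 15.1% (exact permutation p = 0.183), so the call on whole profiles rested on these 137 of 15372 IDs. The lead ID of set A also ran from 0.906 to 4377 CPM among the ELS libraries and from 0.766 to 10590 CPM among the ELS-HFD libraries. Large differences in it thus also arose between daughters within 1 group, and RNA of a neighbouring tissue taken with the sample was not excluded. At an adjusted p of 0.05, edgeR over all libraries called 0 IDs and had 1198 at an unadjusted p under 0.05, where 769 would come by chance on average. IDs vary together, so the number can lie far from that by chance. Other splits of the HFD and control libraries gave a median of 692 and at most 3329. limma-voom called 0, DESeq2 called 5 and the edgeR fit to these 2 groups alone called 3. The 1198 (734 higher and 464 lower in HFD) became 587 without HFD replicate 1, 669 without control replicate 2, 705 without control replicate 1, 1871 without HFD replicate 4 and 2130 without HFD replicate 2. In the edgeR fit to these 2 groups alone it was 770, 335 higher and 435 lower. With the replicate number as a block it was 790. The median SE of a log2 fold change was 0.21.

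**Figure D2:**
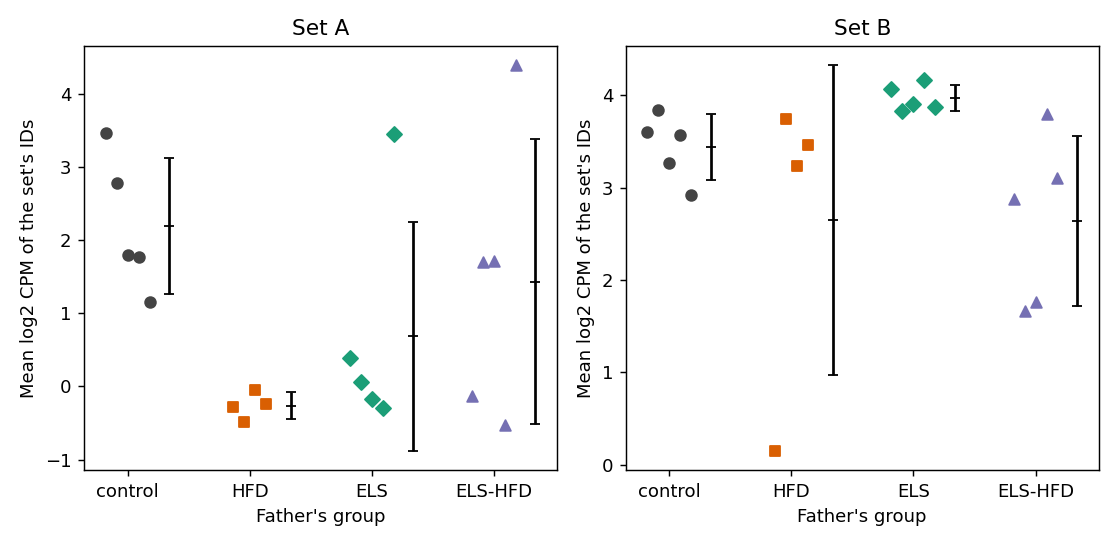
Mean log2 CPM of the 137 IDs of set A (left) and the 81 IDs of set B (right) in each library by father's group, with each group's mean and SD beside its points. In set A the 4 HFD libraries lie between -0.49 and -0.04 and the 5 control libraries between 1.15 and 3.47, and in set B the 5 ELS libraries lie between 3.84 and 4.16.

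The comparison of ELS with control asks the same of the father's early life stress. Set B was at 3.97 ± 0.14 (SD, n = 5) in daughters of ELS fathers and at 3.44 ± 0.35 (SD, n = 5) in controls, a difference of 0.53 (exact permutation p = 0.0159, adjusted p = 0.0762 over 48 tests). Set A was near the level of the HFD libraries in 4 of the 5 ELS libraries, at -0.30 to 0.39, and at 3.45 in ELS replicate 5. Its mean was 0.68 ± 1.57 (SD, n = 5), and the difference from control of -1.51 was within the spread (exact permutation p = 0.111, adjusted p = 0.321). Without ELS replicate 5 the difference was -2.20 (exact permutation p = 0.0159). The group explained 18.4% of the variance between profiles (exact permutation p = 0.0556, adjusted p = 0.0833). edgeR called 0 IDs, with 668 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 1. That number was 1429 without HFD replicate 1, 402 without control replicate 3, 414 without ELS replicate 1 and 2327 in a fit to these 2 groups alone.

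ELS-HFD against control compares daughters of fathers with both exposures with those of fathers with none. Set A spanned -0.52 to 4.40 among the 5 ELS-HFD libraries, which is wider than the whole range of the controls, and its mean of 1.43 ± 1.95 (SD, n = 5) lay 0.76 below control (exact permutation p = 0.413, adjusted p = 0.631). The difference was -0.27 without ELS-HFD replicate 4, -0.37 without ELS-HFD replicate 1, -0.44 without control replicate 1 and -1.50 without ELS-HFD replicate 5 (exact permutation p from 0.0873 to 0.770). ENSRNOG00000016275 ran from 0.766 to 10590 CPM in these libraries. The group explained 14.0% of the variance between profiles (exact permutation p = 0.246, adjusted p = 0.295). edgeR called 0 IDs, with 643 at an unadjusted p under 0.05, and limma-voom and DESeq2 both called 0. Those 643 became 2048 without HFD replicate 1, 1637 without ELS-HFD replicate 4, 349 without control replicate 2, 342 without ELS-HFD replicate 2, 388 without ELS-HFD replicate 3 and 1465 in a fit to these 2 groups alone.

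ELS-HFD against ELS asks what the diet adds among daughters of stressed fathers. Set B was lower in all 5 ELS-HFD libraries than in all 5 ELS libraries, at 2.64 ± 0.92 (SD, n = 5) against 3.97 ± 0.14 (SD, n = 5), a difference of -1.33 (exact permutation p = 0.00794, the smallest that 252 splits can give, adjusted p = 0.0572 over 48 tests). The first principal component separated the same libraries, with a difference of 42.9 (exact permutation p = 0.00794, adjusted p = 0.0572). ELS-HFD replicates 2 and 3 stood apart from the other 3 in both measures, and without them the differences were -0.71 and 22.4 (exact permutation p = 0.0179 for each, the smallest that 56 splits can give). The group explained 20.5% of the variance between profiles (exact permutation p = 0.0476, adjusted p = 0.0833). The ID with the smallest p, ENSRNOG00000049641, was at 30.5 ± 1.75 CPM (SD, n = 5) against 20.8 ± 2.21 CPM (SD, n = 5), with an edgeR log2 fold change of 0.55 ± 0.10 (SE) and an adjusted p of 0.166. edgeR called 0 IDs and had 3039 at an unadjusted p under 0.05, 1342 higher and 1697 lower in ELS-HFD, while limma-voom called 0 and DESeq2 called 151. With 1 surrogate variable 1275 IDs were at an unadjusted p under 0.05, and 1831 and 1804 were without ELS-HFD replicate 2 and without ELS-HFD replicate 3. An edgeR fit to these 2 groups alone called 0 IDs and had 4132 at an unadjusted p under 0.05. Without HFD replicate 1, a library outside this comparison that shares the estimate of the spread, edgeR called 2405 IDs, 1174 higher and 1231 lower, and had 5137 at an unadjusted p under 0.05. Without HFD replicate 1 and ELS-HFD replicates 2 and 3, an alternative chosen after seeing the data, it called 0 and had 2901 at an unadjusted p under 0.05. In ELS-HFD replicates 1, 4 and 5 against ELS, all 2401 of the called IDs kept by the filter over all libraries had the sign of the whole group's difference, at a median 0.718 of its size, though these libraries also took part in choosing them.

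ELS-HFD against HFD asks what early life stress adds among daughters of fathers on the diet. Set A was at 1.43 ± 1.95 (SD, n = 5) against -0.27 ± 0.18 (SD, n = 4), a difference of 1.70 that was within the spread (exact permutation p = 0.127, adjusted p = 0.321) and was 0.96 (exact permutation p = 0.286) without ELS-HFD replicate 5. Set B was at 2.64 ± 0.92 (SD, n = 5) and 2.65 ± 1.68 (SD, n = 4), and HFD replicate 1 lay at 0.15 where the other HFD libraries were at 3.23 to 3.75. The group explained 9.80% of the variance between profiles (exact permutation p = 0.69, adjusted p = 0.69). edgeR called 0 IDs, with 519 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 3. It was 1929 without HFD replicate 1, 897 without ELS-HFD replicate 4, 306 without ELS-HFD replicate 5, and 213 in a fit to these 2 groups alone.

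The interaction asks whether the diet's difference depends on the father's early life. For set A the difference between HFD and control was -2.46, and that between ELS-HFD and ELS was 0.75. The 2 differed by 3.21 (exact permutation p = 0.0249, adjusted p = 0.0995 over 48 tests). The permuted labels assume no diet difference in either setting, so this p is not exact for equal differences in both. The 0.75 was itself within the spread (exact permutation p = 0.524), and was 0.0056 without ELS-HFD replicate 5, 1.44 without ELS replicate 5, 1.14 without ELS-HFD replicate 1, 1.24 without ELS-HFD replicate 4 and 0.50 without ELS replicate 4, the 5 libraries that moved it most. The interaction moved to 2.47 (exact permutation p = 0.0609) without ELS-HFD replicate 5, and to 2.96 (exact permutation p = 0.0503) without ELS replicate 4. edgeR called 0 IDs for the interaction, with 788 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 5. The 788 became 3135 without HFD replicate 1, 1222 without ELS-HFD replicate 4 and 1434 with 1 surrogate variable. Without ELS replicate 5, edgeR called 12 IDs.

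Averaged over diets, the ID with the smallest p for paternal ELS was ENSRNOG00000029386. It was at 5.07 ± 3.44 CPM (SD, n = 5) in control and 5.45 ± 3.36 CPM (SD, n = 4) in HFD libraries, and at 1.30 ± 2.61 CPM (SD, n = 5) in ELS and 0.116 ± 0.131 CPM (SD, n = 5) in ELS-HFD libraries. Of the 10 libraries from daughters of ELS or ELS-HFD fathers, 9 had at most 4 counts and ELS replicate 1 had 89, whereas the other groups had 10 to 126 counts. Its edgeR log2 fold change was -3.61 ± 0.80 (SE), with an adjusted p of 0.995, and without ELS replicate 1 it was -5.26 with an adjusted p of 0.00133. edgeR called 0 IDs, with 382 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 1. The 382 became 645 without HFD replicate 2 and 965 without HFD replicate 4. Without ELS replicate 1, edgeR called 1.

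Paternal HFD averaged over early life compares the 9 daughters of fathers on the diet with the other 10, within each kind of early life. Set B differed by -1.06 in mean log2 CPM (exact permutation p = 0.00835, adjusted p = 0.0572 over 48 tests), and by -0.65 (exact permutation p = 0.033) without HFD replicate 1. The 10 most abundant IDs took 3.43 percentage points more of the counts (exact permutation p = 0.00428, adjusted p = 0.0572), and 1.85 more (exact permutation p = 0.0151) without HFD replicate 1. The ID with the smallest p, ENSRNOG00000029670, was at 9.47 ± 4.27 CPM (SD, n = 4) in HFD and 6.83 ± 3.17 CPM (SD, n = 5) in ELS-HFD libraries, against 3.69 ± 1.2 CPM (SD, n = 5) in control and 2.96 ± 0.508 CPM (SD, n = 5) in ELS libraries. Its edgeR log2 fold change was 1.28 ± 0.23 (SE), with an adjusted p of 0.147. edgeR called 0 IDs and had 3739 at an unadjusted p under 0.05, 2174 higher and 1565 lower with paternal HFD, while limma-voom called 0 and DESeq2 called 306, 222 higher and 84 lower. The balance of directions at an unadjusted p under 0.05 turned with limma-voom, which had 1756 higher and 2272 lower. The number was 2483 without HFD replicate 1 and 891 with 1 surrogate variable. Without HFD replicate 1 and ELS-HFD replicates 2 and 3 the number at an unadjusted p under 0.05 was 1585 and edgeR called 0.

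The fold changes of each exposure in its 2 settings, which share no library, were also compared across the 15372 IDs. IDs are not independent replicates, so the correlation was set against permuted labels. For the diet, HFD minus control correlated with ELS-HFD minus ELS at r = 0.209 (exact permutation p = 0.523), and at r = -0.206 (exact permutation p = 0.326) without HFD replicate 1. Without ELS-HFD replicates 2 and 3 as well it was -0.174 (exact permutation p = 0.456). For early life stress, ELS minus control correlated with ELS-HFD minus HFD at r = -0.369 (exact permutation p = 0.0778), and at r = -0.523 (exact permutation p = 0.00595) without HFD replicate 1. With ELS-HFD replicates 2 and 3 also left out, the latter was -0.430 (exact permutation p = 0.0683). These 6 values were chosen after the data were examined and were not adjusted.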

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

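All tests of explanations in this part were chosen after the result was seen. The splits were fixed before their results were seen, except the splits of HFD against control and those of the counts of 0.

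Of 48 groups of values, 10 held a library far from the rest of its group, where chance gives about 1 in 20 for a single group. The groups are not independent, since 1 library can stand apart in several related measures. The printed IDs were also chosen after their values were seen, so the 10 cannot be set against that rate. HFD replicate 1 stood apart in the share of the 10 most abundant IDs (25.62%), in the first principal component (113.69) and in set B (0.15). ELS replicate 5 stood apart in the second component (38.11), in set A (3.45) and in ENSRNOG00000016275 (12.1 as log2 of CPM plus 1). HFD replicate 4 had a lower total than the other HFD libraries, at 10092297 counts. ELS replicate 1 was high in ENSRNOG00000029386 (2.80 as log2 of CPM plus 1), ELS replicate 4 low in ENSRNOG00000049641 (4.17) and ELS-HFD replicate 1 high in ENSRNOG00000029670 (3.75). The difference that goes with paternal HFD differed between fathers with and without early life stress for set A, by 3.21 (exact permutation p = 0.0249, adjusted p = 0.0995), and for the second component, by 55.98 (exact permutation p = 0.0212, adjusted p = 0.0925). Neither passes after adjustment over 48 tests, and for set A the unadjusted p was 0.0609 without ELS-HFD replicate 5 and 0.0503 without ELS replicate 4 (both exact permutation). The permutations behind these p-values assume no diet difference in either setting, so they are not exact for equal differences in both.

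Set A was high in all 5 control libraries and low in all 4 HFD libraries. It was also low in the ELS libraries, at -0.30 to 0.39, except for ELS replicate 5 (3.45), although these fathers were not on the diet. Over the 9 libraries where its lead ID, ENSRNOG00000016275, reached 100 CPM and spanned a 33.0-fold range, the other members followed it with a median log-log slope of 0.90 (interquartile range 0.69 to 1.05, in the 111 of 136 members that lay above the HFD mean in each of them), and 54.1% of the slopes were between 0.8 and 1.2. For these slopes the mean CPM of the HFD libraries was first subtracted from each ID as background, the lead ID included. The members were clustered by their correlation in these same libraries. That they followed the lead ID was thus in part fixed by the choice, though correlation alone does not set a slope. RNA of 1 source present in varying amount, such as a neighbouring tissue or a cell population taken with the sample, would give slopes near 1. A real difference in the number of such cells would give the same ratio, so the slopes cannot decide between them. No source was named because no marker could be matched. An effect of paternal HFD also stays open, whether limited to fathers without early life stress or not: 3 of the 5 ELS-HFD libraries were above the lowest control library, but the interaction for the set did not pass (exact permutation, adjusted p = 0.0995).

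The number of IDs called in ELS-HFD against ELS went from 0 to 2405 once HFD replicate 1 was left out. The common biological coefficient of variation was then 0.851 of its former value (0.224 against 0.264), so a wider shared spread from that library may account in part for the count of 0. An edgeR fit to the ELS-HFD and ELS libraries alone also lacks HFD replicate 1. It called 0 IDs, with 4132 at an unadjusted p under 0.05. That fit estimates the spread from fewer libraries, so the absence of HFD replicate 1 was not by itself enough for the calls. Fold changes correlated across IDs at r = 1.00 with those of all libraries. The design gives this value in advance, since HFD replicate 1 is in neither group, so it adds no support. Unequal depth is argued against as the cause of the calls, since 2206 were made with all libraries thinned to 7034837 counts. Without the 10 most abundant IDs 2291 were made. This cannot decide whether a few abundant IDs matter, since TMM scaling already limits their weight. The library where they took the largest share, HFD replicate 1, was also left out of that fit. Whether ELS-HFD replicates 2 and 3 alone carry the calls stays open: 0 remained without that pair, and the 4 of 10 pairs of ELS-HFD libraries whose loss left 0 calls each held replicate 2 or 3, while the 3 pairs that spared both left 1948 to 4861 and the other 3 left 49 to 2762. The called IDs kept a median 0.718 of their difference in the other 3 ELS-HFD libraries, which took part in choosing them. The profile that sets HFD replicate 1 apart from the other HFD libraries correlated with ELS-HFD minus ELS at r = 0.671 across IDs, and at r = 0.430 with ELS-HFD replicates 2 and 3 left out, neither set against chance, and a difference that goes with paternal diet among stressed fathers stays open, with its tests given beside the contrast.

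Other splits of the samples were refitted for each contrast, 100 per contrast with the real one included. The numbers of IDs at an unadjusted p under 0.05 were read 1 contrast at a time, with no adjustment for the 8 that were read. In ELS-HFD against ELS 1 of 100 splits, the real one, reached 3039, and the highest other gave 2249. In paternal HFD averaged over early life 1 of 100 reached 3739, and the highest other gave 2700. This argues against chance alone only if the animals are exchangeable, and some may share a father or litter. With 1 surrogate variable these numbers were 1275 and 891, without HFD replicate 1 they were 5137 and 2483, and the test of whole profiles in ELS-HFD against ELS had an adjusted p of 0.0833 by exact permutation. Without HFD replicate 1, 1 of 100 splits reached the 2405 calls of ELS-HFD against ELS and the 5137 IDs at an unadjusted p under 0.05. The highest others gave 2203 and 5128, and 13 of the other splits made calls. Other splits can keep most of the real labels, and which animals changed places in those with calls was not examined. Whether the calls reflect a structure of the samples besides the groups was therefore not tested. With ELS-HFD replicates 2 and 3 left out as well, 3 of the 56 splits of the remaining libraries reached the 2901 IDs at an unadjusted p under 0.05 (highest other 3154), so chance cannot be excluded there, and 56 of 56 reached the 0 calls (highest other 282). Paternal HFD averaged had 1585 IDs at an unadjusted p under 0.05 without these 3 libraries, and no splits were run for that number. Chance cannot be excluded for the unadjusted counts in HFD against control (1198, reached by 20 of 100, highest other 3329), ELS against control (668, 13 of 100, highest other 1139), ELS-HFD against control (643, 22 of 100, highest other 1915), ELS-HFD against HFD (519, 89 of 100, highest other 6507), the interaction (788, or 3135 without HFD replicate 1, for which no splits were run; 28 of 100, highest other 5078) and paternal ELS averaged over diets (382, 72 of 100, highest other 4019). Counts of 0 calls are reached by 100 of 100 splits in all 8 contrasts. The highest number of calls in another split was 2 for HFD against control, 0 for ELS against control and for ELS-HFD against control, 66 for ELS-HFD against ELS, 4525 for ELS-HFD against HFD, 1 for the interaction, 124 for paternal ELS averaged and 1 for paternal HFD averaged.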

How the results depend on the processing

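All 8 contrasts had 0 calls with edgeR, and stayed at 0 calls with RLE scaling, limma-voom, no filter, the stricter filter and robust dispersions. The replicate number as a block also gave 0 calls in every contrast. The numbers do not pair the animals by any label, the 27 same-numbered pairs had correlations of deviations from -0.436 to 0.570, and 6 of 19 libraries correlated best with one of their own number. DESeq2 called 5 IDs for HFD against control, 1 for ELS against control, 0 for ELS-HFD against control, 151 for ELS-HFD against ELS, 3 for ELS-HFD against HFD, 5 for the interaction, 1 for paternal ELS averaged and 306 for paternal HFD averaged. With its independent filtering set for 0.05 it called 5, 1, 0, 146, 3, 5, 1 and 329 in that order, and on all IDs with a count 5, 0, 0, 143, 3, 4, 1 and 262. Both settings were chosen after seeing the data. A fit to only the groups compared called 3 IDs for HFD against control and 0 for ELS-HFD against ELS. With 1 surrogate variable 2 IDs were called for ELS against control and 1 for ELS-HFD against ELS. limma-voom with sample weights, also chosen after seeing the data, gave HFD replicate 1 a weight of 0.0976 and called 2405 IDs for ELS-HFD against ELS, which is by coincidence the number without HFD replicate 1, with 2033 IDs shared.

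Leaving out 1 library at a time gave 0 to 2405 calls for ELS-HFD against ELS (2405 without HFD replicate 1, 1 without ELS-HFD replicate 4), 0 to 12 for the interaction (12 without ELS replicate 5), 0 to 1 for paternal ELS averaged (1 without ELS replicate 1) and 0 to 2 for paternal HFD averaged (2 without HFD replicate 2), and 0 throughout for the other 4 contrasts. Apart from HFD replicate 1, the cause was not tested. The share of variance between the profiles of HFD and control was 15.1% with set A left out (exact permutation p = 0.183) and ran from 18.8% to 27.1% as each library was left out (exact permutation p from 0.0179 to 0.0857), in part because fewer samples allow fewer splits. All alternatives kept the sign of the 4 printed fold changes, and their adjusted p-values from edgeR, DESeq2 and limma ran from 0.00039 to 1.00 for ENSRNOG00000016275, 0.00133 to 1.00 for ENSRNOG00000029386, 0.00112 to 0.416 for ENSRNOG00000049641 and 0.000251 to 0.845 for ENSRNOG00000029670. Without HFD replicate 1 and ELS-HFD replicates 2 and 3, all 8 contrasts had 0 calls, with 2901 IDs at an unadjusted p under 0.05 for ELS-HFD against ELS. The gene-list tests and their alternatives were not run, since no ID could be matched to a symbol. At these depths and spreads the median SE of a log2 fold change was 0.20 to 0.21 for the pairwise contrasts, and in the simulated contrast of HFD against control 65% of IDs changed by a fold of 2 were recovered. The simulation let IDs vary independently and set no library apart from the rest, so the real fit may recover another share.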

Other observations

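ENSRNOG00000029386 took nearly separate high and low values across the libraries, with 10 to 126 counts in all 9 daughters of control and HFD fathers and in ELS replicate 1 (89 counts), and 0 to 4 counts in the other 9 daughters of ELS or ELS-HFD fathers. It was chosen after its values were seen. ELS-HFD replicates 2 and 5 had 0 counts, which allow up to 0.420 and 0.248 CPM, for counting error only. Values of this kind were not traced to a variant, a family or the father's group, since the labels give no father or litter.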
